A study of Homo sapiens with 6 samples.

How the data were processed

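RNA was measured in 6 libraries of human embryonic stem cells (H1), 2 for each of 3 Dicer genotypes, made by iCLIP with an antibody against Ago2. The values are whole-number read counts per gene in the authors' deposited table, with no normalization. Per the submitters' processing notes, the genome build was hg38. The aligner, the counting tool, the annotation, the use of strand and the use of molecular identifiers are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies therefore cannot be told apart with certainty. The lowest row total was 132, so rows with few counts had been removed or were not listed. Control pull-downs with IgG, which the labels' protocol mentions, were not used here. The table's columns were tied to samples by the samples' descriptions, and 0 columns were left unused.

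Of the 16199 rows, 14750 carry a symbol in the RefSeq gene table of assembly GRCh38.p14, 1243 carry an Ensembl identifier with no symbol, and 206 other names did not match. RefSeq served for gene classes and for overlap between genes, and no coordinates are printed. Gene sequences were not used here, so the planned test of targets by microRNA seed match was not run.

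Comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Counts were normalized with TMM factors, filtered with filterByExpr (which kept all 16199 rows) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, in a model with a mean for each of the 3 genotypes over all 6 libraries. The 4 contrasts were hemizygous against wild-type, homozygous against wild-type, the mean of both mutants against wild-type, and homozygous against hemizygous. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM, the counts per library scaled to a common total, use the TMM factors, and SDs are over 2 libraries. Standard errors of fold changes were taken from the fold change and its F value.

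Of 21 gene lists, 19 had at least 5 measured members and were tested with camera of limma 3.58.1 on log2 CPM at a correlation preset at 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The call was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in a direction and does not compare them with other genes. The rule for named genes was to name up to 12 called genes per direction in which the libraries of the groups did not overlap and, if none passed, the 5 with the smallest p in each direction. DICER1 and AGO2 were named in advance. List members given as examples were chosen after their values were seen. Rows without a symbol were counted and not named.

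Alternatives were RLE, upper-quartile and library-size scaling, no filter and a filter of 20 counts in 2 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, and each library left out. Libraries held 38.2 M to 52.9 M counts, and counting error is small beside the spread between libraries at this depth except for genes near 1 CPM and below. A few alternatives were added after seeing the data, and the closing section names them. The pipeline was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 of 16199 genes changed. For hemizygous against wild-type, 48.0% of genes changed by 1 on the log2 scale were called and 96.0% of those changed by 2, with 12 unchanged genes called. For homozygous against wild-type the shares were 38.0% and 86.0%, with 16 unchanged genes called. For both mutants they were 54.0% and 90.0%, with 17, and for homozygous against hemizygous 36.0% and 82.0%, with 20. The simulation holds no structure shared by libraries of a replicate number. In 20 simulated draws for homozygous against wild-type, camera called a list of 25 genes shifted by 0.5 in all 20 and 1 of 360 unshifted lists. Genes were drawn independently of each other, so the draws cannot show how often camera calls lists whose genes vary together.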

Results

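The series measured RNA in H1 cells, an established line of human embryonic stem cells, that carried wild-type Dicer or the S1344L substitution of Dicer. Dicer is the RNase III enzyme that cuts microRNA precursors, and the substitution lies at what the series title calls a hotspot. The labels give 3 genotypes, wild-type, S1344L hemizygous and S1344L homozygous, with 2 libraries each. Cells had grown for 10 days without doxycycline, were exposed 2 times to 254 nm light at 150 mJ/cm2, and RNA was recovered with an antibody against Ago2. Ago2 is the Argonaute protein that holds a microRNA on its target. The method, iCLIP, crosslinks protein to RNA and sequences what stays bound. The deposited table held counts for 16199 genes. Nothing in the labels says that the 2 libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

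Total counts were 52.9 M and 38.2 M in the wild-type libraries, 39.7 M and 51.6 M in the hemizygous and 46.2 M and 39.6 M in the homozygous. The 10 most abundant genes took 7.12% to 8.21% of the counts. Protein-coding genes took 88.0% to 89.7% of the counts, and mitochondrial rows took 6.59% to 7.91%. The most abundant row was MT-CO1, a mitochondrial respiratory chain subunit, at a mean of 1.64% of counts, and EEF1A1, a translation elongation factor, stood at 0.945%. Only 9 rows were microRNA hairpins. They held between 0.00203% (95% exact binomial interval 0.00190% to 0.00217%, homozygous replicate 1) and 0.00275% (interval 0.00259% to 0.00292%, homozygous replicate 2) of a library. These intervals cover counting error only. MIR1244-2 alone held 715 of the 1161 counts in these rows in wild-type replicate 1. In homozygous replicate 2 it held 549 of 1090, so the share rests largely on that row. The share in microRNA rows was 0.00230% ± 0.000148 (SD, n = 2) in wild-type and 0.00222% ± 0.000239 (SD, n = 2) in hemizygous libraries. It was 0.00239% ± 0.000511 (SD, n = 2) in homozygous libraries. The exact two-sided permutation test gave p = 0.667 for hemizygous against wild-type (n = 2 each) and p = 1 for homozygous. With 2 libraries against 2 this test cannot go below 0.333. Each of the lists of 5p-guide and 3p-guide hairpins had 1 measured member, MIR186 and MIR25, so neither was tested. Given this content, the values below are described as counts in libraries labelled Ago2 iCLIP. Whether they follow Ago2 binding or transcript level was not settled by the table.

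Wild-type and hemizygous libraries separated by replicate number more than by genotype. Homozygous replicate 1 followed its number more weakly and correlated more with the replicate 2 libraries than with the other replicate 1 libraries. The first principal component held 59.1% of the variance of log2 CPM (counts scaled to library size). It placed wild-type replicate 1 at -34.48 and hemizygous replicate 1 at -39.80, and homozygous replicate 1 at 3.15. The replicate 2 libraries stood at 20.58, 22.03 and 28.52. Across genes, which are not independent replicates, wild-type replicate 1 correlated with hemizygous replicate 1 at a Pearson r of 0.993 and with wild-type replicate 2 at 0.982. Homozygous replicate 1 correlated at 0.990 with hemizygous replicate 2, at 0.989 with homozygous replicate 2 and with wild-type replicate 2, and at 0.985 with replicate 1 of each other genotype. Homozygous replicate 2 correlated at 0.994 with hemizygous and 0.991 with wild-type replicate 2. Genes of the fibroblast and stromal list, which includes collagens, had a median log2 difference of 0.48 between replicate 1 and 2 in wild-type and 0.54 in hemizygous libraries. In homozygous libraries it was 0.08. Mesendoderm markers differed in the same way, by 1.09, 0.73 and 0.34.

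**Figure D1:**
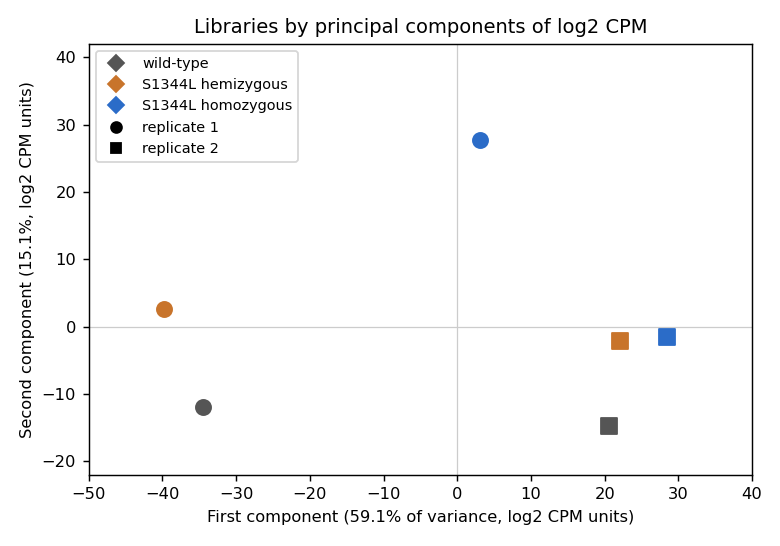
Each point is a library, placed by its first (horizontal) and second (vertical) principal component of log2 CPM, with color for genotype and shape for replicate number. Replicate 1 of wild-type (-34.48) and of hemizygous (-39.80) lie far to the left of the other 4 libraries.

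DICER1 itself was counted in every library. Its level was 148 ± 30.6 CPM (SD, n = 2) in wild-type, 107.4 ± 15.6 in hemizygous and 123 ± 7.80 in homozygous libraries. The log2 fold change was -0.46 (SE 0.19) in hemizygous and -0.26 (SE 0.19) in homozygous cells, with an adjusted p of 1.00 by edgeR's quasi-likelihood test in both. A substitution need not alter a gene's count, so these levels do not check S1344L itself. The comparisons took the hemizygous genotype as an S1344L allele over a frameshift allele, which is more than a substitution. There DICER1 was lower in both libraries (118 and 96.4 CPM) than in both of wild-type (169 and 126). Such separation, in either direction, was seen in 17.3% of all genes in this comparison, where chance gives 33.3%. The unadjusted p of DICER1 by edgeR was 0.0456, and the cause was not tested. AGO2 stood at 220 ± 2.61 CPM (SD, n = 2), 254 ± 32.2 and 233 ± 48.7, with log2 fold changes of 0.21 (SE 0.18) and 0.08 (SE 0.18). The homozygous value of AGO2 was -0.15 without homozygous replicate 1.

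**Figure D2:**
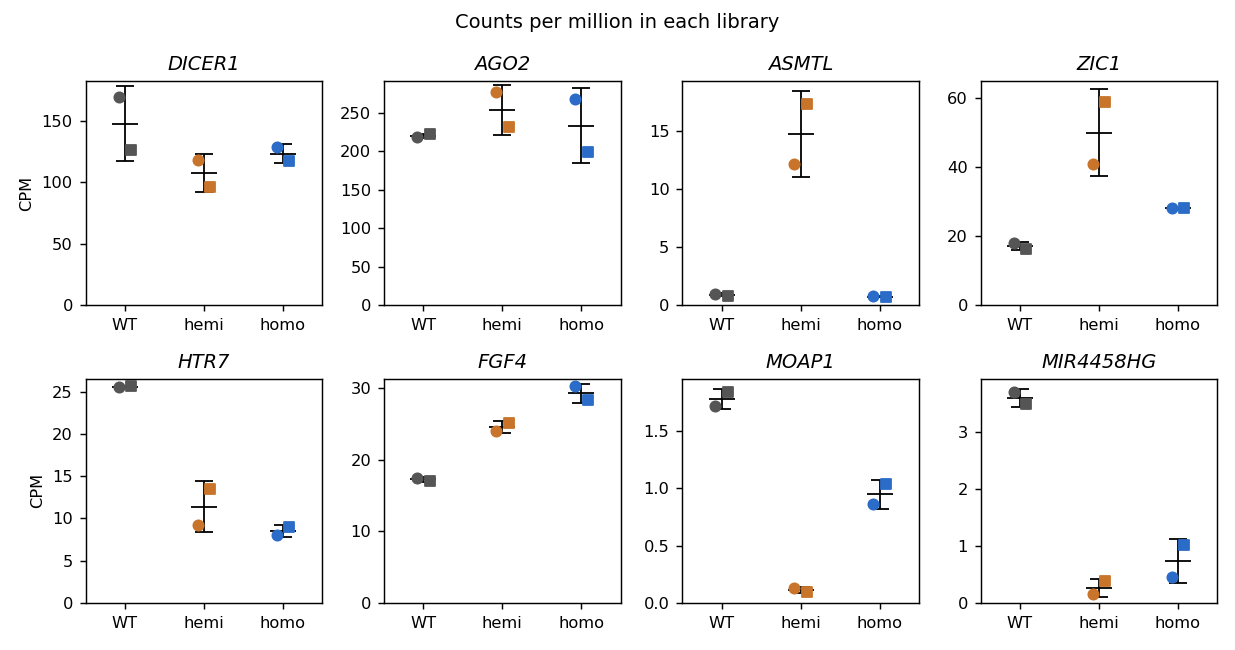
CPM (vertical axes, from 0) of 8 genes in each library by genotype (WT, wild-type; hemi, hemizygous; homo, homozygous). Circles are replicate 1, squares replicate 2, and bars the mean with SD (n = 2); ASMTL is at 12.1 and 17.3 CPM in the hemizygous libraries and near 1 CPM in the rest.

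The first comparison asks what S1344L in the hemizygous state does to the counts. ASMTL, a gene of the pseudoautosomal region, stood at 14.7 ± 3.68 CPM (SD, n = 2) in hemizygous against 0.898 ± 0.148 in wild-type libraries, a log2 fold change of 4.02 (SE 0.30). ZIC1, a transcription factor of the neural plate, stood at 49.9 ± 12.6 against 17.1 ± 1.14 CPM, a log2 fold change of 1.54 (SE 0.20). Lower counts were seen for HTR7, a serotonin receptor, at 11.4 ± 3.02 against 25.6 ± 0.0750 CPM (log2 fold change -1.16, SE 0.21). MOAP1, a modulator of apoptosis, was at 0.113 against 1.78 CPM (log2 fold change -3.97, SE 0.38), and MIR4458HG, a microRNA host gene, at 0.268 against 3.59 CPM (log2 fold change -3.68, SE 0.53). None of these passed edgeR's test in the model of 3 genotype means. edgeR's quasi-likelihood test called 0 of 16199 genes, and 141 had an unadjusted p under 0.05 (74 higher, 67 lower) where 810 would be reached by chance. The number lay under that of chance in the later comparisons too. The test was therefore conservative, and 0 calls do not show that no gene differs. limma-voom called 0. DESeq2 called 7, among them ASMTL, ZIC1, HTR7, MOAP1 and MIR4458HG. The lowest adjusted p by edgeR was 0.0694, for ASMTL, and MOAP1 followed at 0.178. With the replicate number as a block, edgeR called 1 gene, ASMTL (adjusted p = 0.0127). The other genes with the smallest p in each direction were ZNF677, ANKRD46 and NEB, with log2 fold changes of 0.94, 0.54 and 0.74, and ZNF492 and ZNF849P, with -2.38 and -2.76. ASMTL overlaps an antisense RNA, and ZNF492 and ZNF849P belong to a large family with similar copies, so their counts are uncertain. Leaving out a library moved the count of called genes to 1 without wild-type replicate 1, to 2 without hemizygous replicate 1 and to 2 without hemizygous replicate 2.

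Neural lineage markers were the only list called in hemizygous cells. The neuroectoderm list was called higher than the other genes by limma's camera test with a preset correlation (adjusted p = 0.00332), with 7 of its 12 measured members above 0 and a median log2 fold change of 0.06. The adjusted p with an estimated correlation was 0.548. ZIC1 was 1 called gene when adjusted over the list alone, against 0 over all genes. DCX, which binds microtubules in young neurons, had a log2 fold change of 0.76 (SE 0.22) and FABP7, a fatty acid binding protein of radial glia, 0.75 (SE 0.28), neither called by edgeR. The list's adjusted p was 0.226 without wild-type replicate 2 and 0.238 without hemizygous replicate 1. In every other list tested, 0 genes were called when adjusted over the list alone by edgeR.

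The second comparison asks the same of homozygous cells. FGF4, a growth factor made by pluripotent cells, stood at 29.2 ± 1.36 CPM (SD, n = 2) in homozygous against 17.3 ± 0.336 in wild-type libraries, a log2 fold change of 0.76 (SE 0.13). HTR7 was again lower, at 8.50 ± 0.683 CPM, with a log2 fold change of -1.59 (SE 0.22). B3GALT5, a galactosyltransferase that builds glycolipids, stood at 64.1 ± 1.85 against 119 ± 14.5 CPM (log2 fold change -0.90, SE 0.18). PCDHB17P, a protocadherin pseudogene, was at 1.95 against 0.417 CPM (log2 fold change 2.22, SE 0.30). None passed edgeR's test. edgeR's quasi-likelihood test called 0 genes of 16199, and 435 genes had an unadjusted p under 0.05 (192 higher, 243 lower). limma-voom called 0. DESeq2 called 10, among them HTR7, FGF4, B3GALT5, PCDHB17P, ZNF600 and CALCR. It also called NDUFS1, NOMO1 and FBL, whose replicates differed over 4-fold in a genotype. In wild-type replicates 1 and 2, NDUFS1 was at 10.6 and 2.43 CPM and FBL at 3.18 and 20.6 CPM. The remaining genes with the smallest p were ZNF600, CALCR and PCDHGA6, with log2 fold changes of 0.87, 1.16 and 1.06, and SMN2, MIR4458HG and SORCS2, with -2.91, -2.29 and -1.49. SMN2 has the near-identical copy SMN1 and PCDHGA6 shares exons with its cluster, so both are uncertain. Without wild-type replicate 1, or without hemizygous replicate 1, edgeR called 1 gene.

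In homozygous cells camera with a preset correlation called the ribosomal protein list higher, and the fibroblast and stromal list lower, than the other genes, with no member called. Of 62 measured cytosolic ribosomal protein genes, 59 were above 0, with a median log2 fold change of 0.17 (adjusted p = 2.7e-05, and adjusted p = 0.948 with an estimated correlation). RPL11 and RPS12 had log2 fold changes of 0.17 (SE 0.18) and 0.15 (SE 0.17). Of 22 measured fibroblast and stromal genes, 19 were below 0, with a median of -0.35 (adjusted p = 0.00218, and adjusted p = 0.948 with an estimated correlation). PDGFRB, a growth factor receptor, had a log2 fold change of -0.85 (SE 0.33) and COL1A2, a collagen chain, -0.44 (SE 0.19). By edgeR, 0 members of either list were called, over all genes or adjusted over the list alone. Stromal genes were also higher in replicate 1 than in replicate 2 of the other genotypes, as given above. Between libraries of the same number the stromal median was -0.51 for replicate 1 and -0.08 for replicate 2. The ribosomal median was 0.16 for replicate 1 and 0.17 for replicate 2. The stromal list's adjusted p was 0.485 without wild-type replicate 1 and 0.147 without homozygous replicate 2, and that of the ribosomal list was 0.218 without homozygous replicate 2.

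**Figure D3:**
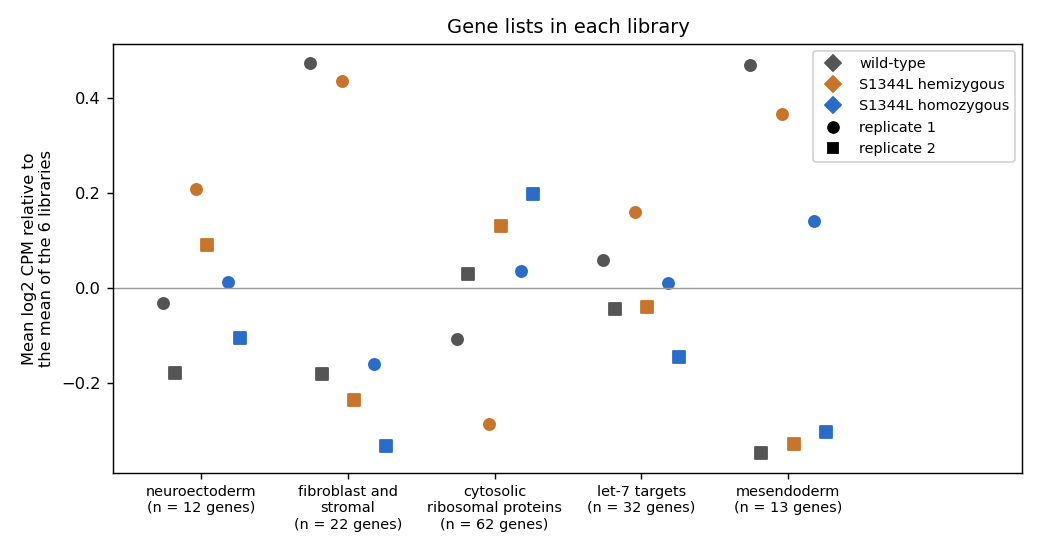
Mean log2 CPM of the measured genes of 5 lists in each library, relative to the mean of the 6 libraries (vertical axis), by list (horizontal axis), with color for genotype and shape for replicate number. The stromal list is at 0.47 and 0.44 in replicate 1 of wild-type and hemizygous, and below 0 in the other 4 libraries.

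The mean of both mutant genotypes was then set against wild-type. HTR7 (log2 fold change -1.38, SE 0.18), MIR4458HG (-2.99, SE 0.40) and MOAP1 (-2.44, SE 0.27) were lower, and FGF4 (0.63, SE 0.12), ANKRD46 (0.52, SE 0.11), ZIC1 (1.13, SE 0.18) and PCDHB17P (1.44, SE 0.28) higher, none past the test. ASMTL had a log2 fold change of 1.87 (SE 0.26), which came from the hemizygous libraries, since it stood at 0.742 CPM in the homozygous. MTCH2 and NDUFS1, both mitochondrial proteins, had -2.92 (SE 0.60) and -2.50 (SE 0.52), with MTCH2 at 14.4 CPM in homozygous replicate 1 and 2.12 in replicate 2, and NDUFS1 at 10.6 CPM in wild-type replicate 1 and 2.43 in replicate 2. edgeR's quasi-likelihood test called 0 genes, with 314 genes at an unadjusted p under 0.05 (142 higher, 172 lower). limma-voom called 0. DESeq2 called 10, among them HTR7, MIR4458HG, MOAP1, FGF4, ZIC1, ASMTL and NDUFS1. It also called NOMO1 and FBL, whose replicates, like those of NDUFS1, differed over 4-fold in a genotype. Camera called 0 of 19 lists, with 5 lists at an unadjusted p under 0.05, and fry called 0. Adjusted over the list alone, 2 neuroectoderm genes were called, ZIC1 and FABP7, against 0 over all genes. Both sets of mutant libraries share the same 2 wild-type libraries, so this comparison is not independent of the former. Leaving out wild-type replicate 1 gave 2 called genes and 6 called lists, and leaving out wild-type replicate 2 gave 5 lists.

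The last comparison asks whether the mutant genotypes differ. ASMTL was lower in homozygous than hemizygous libraries (log2 fold change -4.30, SE 0.30), with the lowest adjusted p of edgeR's quasi-likelihood test at 0.0515. MYH14, a nonmuscle myosin, stood at 65.1 ± 2.75 CPM (SD, n = 2) in homozygous and 34.4 ± 3.75 in hemizygous libraries, a log2 fold change of 0.92 (SE 0.17), and was at 62.5 ± 11.4 in wild-type. ZIC1 (-0.83, SE 0.19), ZNF677 (-0.74, SE 0.18), PRTG (-0.71, SE 0.17) and the pseudogene FAM3C2P (-2.13, SE 0.45) were lower, and MOAP1 (3.06, SE 0.39), ZNF492 (2.72, SE 0.40), ZNF849P (2.72, SE 0.49) and REC8 (5.23, SE 0.83), a meiotic cohesin, higher. None passed. edgeR's quasi-likelihood test called 0 genes, and 124 genes had an unadjusted p under 0.05 (65 higher, 59 lower). limma-voom called 0. DESeq2 called 10, among them ASMTL, MYH14, REC8, MOAP1, ZNF492 and FAM3C2P. Without hemizygous replicate 1, edgeR called 3. With the replicate number as a block, it called 1 gene, ASMTL (adjusted p = 0.00940).

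Camera with a preset correlation called 4 lists between the mutant genotypes. Ribosomal proteins were higher in homozygous cells (median log2 fold change 0.19, 60 of 62 members above 0, adjusted p = 2.07e-09). Fibroblast and stromal genes (median -0.35, 19 of 22 below 0, adjusted p = 0.00250), neuroectoderm markers (median -0.28, 8 of 12 below 0, adjusted p = 0.0130) and described let-7 targets (median -0.13, 23 of 32 below 0, adjusted p = 0.0197) were lower. With an estimated correlation the adjusted p was 0.893 for all 4. Examples are FBN1 (log2 fold change -1.02, SE 0.55) and COL1A1 (-0.54, SE 0.27), both matrix proteins, MAP2 (-0.66, SE 0.27), a neuronal microtubule protein, and the let-7 targets IGF2BP3 (-0.28, SE 0.13) and HMGA2 (-0.23, SE 0.12). RPL11 and RPS12 had 0.16 (SE 0.18) and 0.26 (SE 0.17). No member was called over all genes. Adjusted over the list alone, 1 neuroectoderm gene, ZIC1, was called. All 4 calls ended without hemizygous replicate 1, with adjusted p values of 0.836 for ribosomal proteins, 0.636 for stromal genes, 0.0660 for neuroectoderm and 0.636 for let-7 targets, and the ribosomal direction was then down. Without homozygous replicate 2 the adjusted p was 0.114 for stromal genes, 0.268 for neuroectoderm and 0.632 for let-7 targets, while ribosomal proteins stayed called at 0.0424. Without hemizygous replicate 2 it was 0.0634 for neuroectoderm. Between libraries of the same number the ribosomal median was 0.35 for replicate 1 and 0.08 for replicate 2, and replicate 1 of the hemizygous cells was the library lowest in ribosomal protein genes.

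Apart from let-7 targets, called between the mutant genotypes, the remaining lists were not called in any comparison by camera on all 6 libraries. Several were called with a library left out. In homozygous against wild-type cells, the adjusted p was 0.899 for microRNA machinery, primed pluripotency, miR-17~92 targets, miR-92 and miR-25 family targets, p53 targets, trophoblast and amnion, cell cycle, nuclear and small structural RNAs, and apoptosis. It was 0.162 for miR-302 family targets, 0.434 for let-7 targets, 0.626 for mesendoderm, 0.678 for mitochondrial transcripts, 0.128 for histones, 0.112 for the integrated stress response and 0.747 for TGF-beta, Activin and Nodal genes. KDR, a growth factor receptor of mesoderm, had log2 fold changes of 0.45 (SE 0.14) in hemizygous and 0.47 (SE 0.14) in homozygous cells, and LEFTY1, a Nodal antagonist and miR-302 target, had -2.71 (SE 0.94) in homozygous cells, neither called.

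Which lists were called moved with the library left out, in hemizygous cells in opposite directions. The lone library of a genotype was then assumed to vary like those of the other genotypes, so these calls also carry the gap between its replicates, such as a median of 0.45 for p53 targets between wild-type replicate 1 and 2. Ribosomal proteins, not called there, were higher by camera without hemizygous replicate 1 (adjusted p = 3.31e-06) and lower without hemizygous replicate 2 (1.96e-09). Targets of p53 were higher without wild-type replicate 1 (0.00273) and lower without wild-type replicate 2 (0.0349). Mesendoderm (3.23e-04), miR-92 and miR-25 family targets (3.23e-04) and TGF-beta genes (0.00499) were also higher, and histones lower (0.00526), without wild-type replicate 1. Stromal and stress response genes were lower without wild-type replicate 2 (0.00648 for both), and stromal genes without hemizygous replicate 1 (0.0130). Without hemizygous replicate 2, let-7 targets and mitochondrial transcripts (0.0378 for both) and miR-92 and miR-25 family targets (0.00464) were higher.

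In homozygous against wild-type cells, camera called mesendoderm higher and histones lower without wild-type replicate 1 (adjusted p = 1.65e-04 for both), and p53 targets and miR-92 and miR-25 family targets higher (0.0485 for both). Without wild-type replicate 2, p53 targets were lower (0.0153), as were stress response (0.00759) and TGF-beta genes (0.0153). For both mutants against wild-type, the lists called with a library left out included mesendoderm, higher without wild-type replicate 1 (7.93e-05), stromal genes, lower without wild-type replicate 2 (1.82e-04), and ribosomal proteins, higher without hemizygous replicate 1 (2.87e-07). Targets of p53 again turned, higher without wild-type replicate 1 (0.00372) and lower without wild-type replicate 2 (0.0164), and TGF-beta genes did so too (0.0246 and 0.0235). Between the mutant genotypes, TGF-beta genes were lower without hemizygous replicate 2 (0.0189) or homozygous replicate 1 (0.0158), as were miR-92 and miR-25 family targets without hemizygous replicate 2 (0.0189). Without wild-type replicate 1 these values were 0.0448 for TGF-beta genes and 0.0380 for miR-92 and miR-25 family targets, and without wild-type replicate 2 they were 0.0450 and 0.0381.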

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

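The tests of the batch and of the other-cell explanation below were chosen after the result was seen, as were the test of counts in microRNA rows and, in the last paragraph, those on counting noise and on the rows that do not follow the replicate number.

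The gene lists called between the mutant genotypes were a difference between groups by its own test. The medians of homozygous minus hemizygous were 0.19 for cytosolic ribosomal proteins, -0.35 for fibroblast and stromal genes, -0.28 for neuroectoderm and -0.13 for let-7 targets, and all 4 calls depended on hemizygous replicate 1. With an estimated correlation the adjusted p was 0.893 for all 4, and with fry 0.969, so none was called by either.

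The wild-type and hemizygous libraries split by replicate number, with 59.1% of the variance on the first component; homozygous replicate 1 lay between. Library depth is argued against, since the component kept 58.5% after every library was thinned to equal depth, with every replicate 1 library still below every replicate 2 library. A larger share of other cells of every kind is also argued against, because the lists moved apart: the lowest median, of trophoblast and amnion genes in wild-type, was -0.25 while mesendoderm genes stood at 1.09. More mesendodermal or stromal cells in those libraries stays open. A batch shared by libraries of the same number also stays open. The lowest correlation of deviations between same-numbered libraries was 0.357. That value cannot decide, since it restates the split and any cause shared by libraries of a number would give it. Beyond cell content, no biological explanation was tested.

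The content of the table resembled a transcriptome. If the counts followed Ago2-bound RNA, microRNA rows would be expected to hold a sizeable share. The highest share in a library was 0.00275%. Mitochondrial rows, taken here to lie outside the reach of cytoplasmic Ago2, held at least 6.59%. The counts may therefore follow transcript levels or background RNA. A counting step that drops short or multiply mapped reads would also lower the microRNA share and stays open.

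In 154 rows the replicates of a genotype differed over 4-fold. Counting error of independent reads is argued against for most, since an exact binomial test adjusted over all genes and genotypes left 7.14% of them (11) at an adjusted p of 0.05 or more; those 11, and reads copied by amplification for all, stay open. In the 133 of them matched to RefSeq, overlap with another RefSeq gene (odds ratio 0.888, upper 95% bound 1.27) and a pseudogene of the same root symbol (0.750, upper bound 1.31) were no more frequent than in other rows by Fisher's exact test. However 99 of the 154 followed the replicate number in wild-type and hemizygous libraries; for the other 55, of which 48 were matched, the odds ratios were 1.06 (upper bound 1.97) and 1.68 (upper bound 3.44), too wide to decide, so shared reads cannot be told apart from other causes there. No biological explanation was tested.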

How the results depend on the processing

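Alternatives that left out erratic rows, mitochondrial rows or wild-type replicate 1 with hemizygous replicate 1 were chosen after seeing the data. In the order hemizygous, homozygous, both mutants and homozygous against hemizygous, edgeR called 0 genes; RLE, library-size and upper-quartile scaling, limma-voom, mitochondrial rows left out and, where run, only the groups compared also gave 0. Both filters removed no gene and so tested nothing. DESeq2 called 7, 10, 10 and 10. Without single libraries the counts ranged over 0 to 2, 0 to 1, 0 to 2 and 0 to 3. With wild-type replicate 1 and hemizygous replicate 1 left out together they were 12, 21, 19 and 16, on 1 residual degree of freedom. With erratic rows left out they were 1 in the first and the last comparison. The cause of these changes was not tested.

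With the replicate block, edgeR called 1 gene (ASMTL) in the first and 1 (ASMTL) in the last comparison, with adjusted p values of 0.0127 and 0.00940, and 0 in the others; with erratic rows also left out it called 5, 0, 5 and 1. Same-numbered libraries deviated together (correlations 0.741, 0.357 and 0.476), but with 2 numbers the libraries share only a number. The common dispersion, a measure of the spread between libraries over all genes, was 0.0397 without the block and 0.0129 with it. The replicate block left the number of called lists as it was.

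Lists called were 1, 2, 0 and 4. An estimated correlation and fry each gave 0, 0, 0 and 0. Without single libraries the ranges were 1 to 6, 0 to 5, 0 to 6 and 0 to 6, and without the pair of replicate 1 libraries 5, 4, 5 and 1.

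Among named genes, direction turned for AGO2 and RPL11; the cause was not tested. Without single libraries the log2 fold change of AGO2 ranged from -0.147 to 0.282 in homozygous against wild-type and from -0.352 to 0.0766 in homozygous against hemizygous, and that of RPL11 in the latter from -0.0454 to 0.413. Without the pair, the latter were 0.0137 for AGO2 and -0.0454 for RPL11. The ribosomal list of homozygous against hemizygous turned down without hemizygous replicate 1 (adjusted p = 0.836) and without the pair (0.754). The tests of microRNA seed matches were not run.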

Other observations

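The genes named here and the test of proteasome subunits were chosen after the values were seen. Several genes were listed at a few CPM or less with a jump in a single library. EEF1B2, a translation elongation factor, stood at 65.0 CPM in wild-type replicate 2 and between 2.25 and 4.69 in the other libraries. FBL, a nucleolar methyltransferase, stood at 20.6 CPM in that library and at most 3.18 elsewhere. ITPK1, an inositol kinase, stood at 28.0 CPM in hemizygous replicate 2 and at most 1.33 elsewhere. Among 30 measured proteasome subunits, whose proteins are made in equal amounts, the median was 126 CPM, and 3 (PSMA2, PSMA6 and PSMB3) lay under 10% of it, at 5.72, 9.41 and 1.74 CPM, with PSMA1 next at 15.5 CPM. Of these 3, 2 overlapped another RefSeq gene, against 10 of the other 27 (Fisher's exact test, p = 0.548). With only 3 such subunits the test could not go under 0.05 even if all 3 overlapped, so it cannot decide.

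A few genes differed widely between replicates. COL12A1, a collagen, stood at 205 and 264 CPM in replicate 1 of wild-type and hemizygous cells and at 10.9 and 7.84 in replicate 2, and ANXA1, a phospholipid-binding protein, at 34.1 and 25.8 against 2.05 and 1.16 CPM. In homozygous cells COL12A1 was at 15.97 and 11.4 CPM in the replicates. EGR1 and DDIT4, which respond to growth factors and stress, were at 17.1 and 149 CPM in homozygous replicate 1, against 3.00 and 35.8 CPM in homozygous replicate 2.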
